A study of Mus musculus with 8 samples.

How the data were processed

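Total RNA of sorted DN3 cells was labelled by a two-cycle protocol from 15 to 100 ng per sample, per the labels, and hybridised to Affymetrix mouse arrays. The labels give RNA amounts of 100, 50 and 15 to 100 ng for different experiment codes that are not mapped to samples. The deposited values are log2 values made by the authors with RMA (background correction, quantile normalization between arrays and a median polish summary per probe set). The version of RMA and whether these 8 arrays were summarised alone are not stated. They were used as deposited. The dose of GSI is given as 5 mM in the labels and could not be checked.

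Groups were taken from the sample titles: WT DMSO, WT GSI, IkL/L DMSO and IkL/L GSI, 2 arrays each. Of 45101 probe sets, 64 controls, 932 naming several genes and 9160 not listed with a gene in the platform annotation were left out of the gene-level tests. For 9010 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which gave 18193 genes, with no filter on dim probe sets.

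Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a mean-variance trend) on all 8 arrays with the 4 groups as terms, 4 residual degrees of freedom and 4.11 prior degrees of freedom. The 6 contrasts were GSI minus DMSO in WT, the same in IkL/L, the average of these, their difference (IkL/L minus WT, the interaction), and IkL/L minus WT under DMSO and under GSI. A gene was called at a Benjamini-Hochberg adjusted p below 0.05; tests were two-sided. Gene values are log2 differences with the moderated standard error (SE), and group values are means with the standard deviation (SD) of 2 arrays. The number of arrays limits the precision of each value.

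The contrasts, tests, 28 gene lists and rule for named genes were fixed before the data were examined. The lists covered Notch targets, Notch pathway components, T lineage genes, genes of later thymocytes, progenitors, ribosome biogenesis, G1/S, G2/M, glycolysis, the ATF4 and amino acid response, cholesterol synthesis, FOXO and quiescence, p53 targets, cell death, interferon-stimulated genes, the Ikaros family, cytokines and effector genes, the respiratory chain, ribosomal proteins, heat shock, immediate early genes, sex-linked genes, and markers of stromal, B, myeloid and dendritic, natural killer and innate lymphoid, gamma-delta T, and erythroid cells. Of their 577 genes 512 were measured; the others were not analysed here. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a contrast, with an estimated correlation and with fry beside it. Counts adjusted over the list alone used the members' p-values only.

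In each contrast the rule named, among called genes whose groups did not overlap, the 10 with the largest increase and the 10 with the largest decrease, without symbols ending in Rik, starting with Gm and digits, or given as accessions. Where fewer than 5 passed, the next genes by p were added up to 5 as not passing. From each list up to 4 members that passed were added, or the 2 largest as not passing where fewer than 2 passed. Ikzf1, Hes1, Dtx1, Nrarp, Notch1, Notch3, Ptcra, Il2ra and Myc were taken always. Genes outside the rule are said to be named after their values were seen.

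Overlaps were set against the product of both counts over the genes tested. Alternatives tried were the replicate number as a block, a mean over a gene's probe sets, all probe sets as features, only genes above the median level, quantile normalization once more, centring on array medians, eBayes without a trend, only the arrays compared, a 2-fold minimum and leaving out each array in turn. A group left with a single array was then assumed to vary like the others. A fit without both WT arrays numbered 1, and fits with the mean stromal marker level or the GAPDH 3' minus 5' difference of each array as a covariate, were added after the data were seen.

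The tests were checked on simulated data with 100 genes changed by a log2 value of 1 and 100 by 2. Of these, 52 and 98 were recovered for GSI in WT, 56 and 92 for the genotype under DMSO, 85 and 100 for the average and 23 and 75 for the interaction, with 7, 8, 6 and 8 false calls. The simulated noise was independent between genes and arrays, so these counts do not cover noise shared between them. Tables were prepared with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots drawn with matplotlib 3.10.9.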

Results

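Gene expression was measured on 8 Affymetrix mouse arrays in 4 groups of 2. The groups were thymocytes of wild-type (WT) and Ikaros-deficient (IkL/L) mice, each treated for 16 h with a gamma-secretase inhibitor (GSI; MRK-003, 5 mM as labelled) or with its vehicle, DMSO. Lineage-negative thymocytes were cultured on OP9 DL1, a stromal cell line that presents a Delta-like Notch ligand, and DN3 cells were then sorted as lineage-negative, CD44-negative and CD25-positive. DN3 cells are early T cell precursors that depend on Notch signals. Gamma-secretase is the protease that frees the intracellular part of a Notch receptor, and Ikaros is a zinc finger transcription factor encoded by Ikzf1. The series compared the response to GSI between the genotypes. The 45101 probe sets of each array covered log2 values from 2.32 to 14.61, with array medians between 5.25 and 5.33, and the replicates of a group correlated across probe sets with r between 0.975 and 0.993. Of 18193 genes tested, 390 lay over 2-fold apart between the replicates of WT DMSO, 830 in WT GSI, 153 in IkL/L DMSO and 146 in IkL/L GSI. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

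The targeted gene was examined first. Ikzf1 was at a log2 level of 12.06 ± 0.16 (SD, n = 2) in WT DMSO, 12.07 ± 0.16 in WT GSI, 11.16 ± 0.04 in IkL/L DMSO and 11.64 ± 0.17 in IkL/L GSI. It was lower in IkL/L than in WT by a log2 difference of -0.90 ± 0.14 (SE) under DMSO (limma, adjusted p = 0.022) and by -0.43 ± 0.14 under GSI (adjusted p = 0.30, not past the threshold). The call under DMSO was lost without any of the 4 DMSO arrays in turn. Where this probe set lies relative to the altered part of the gene is not known here, and a probe set outside that part does not check the labels.

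**Figure D1:**
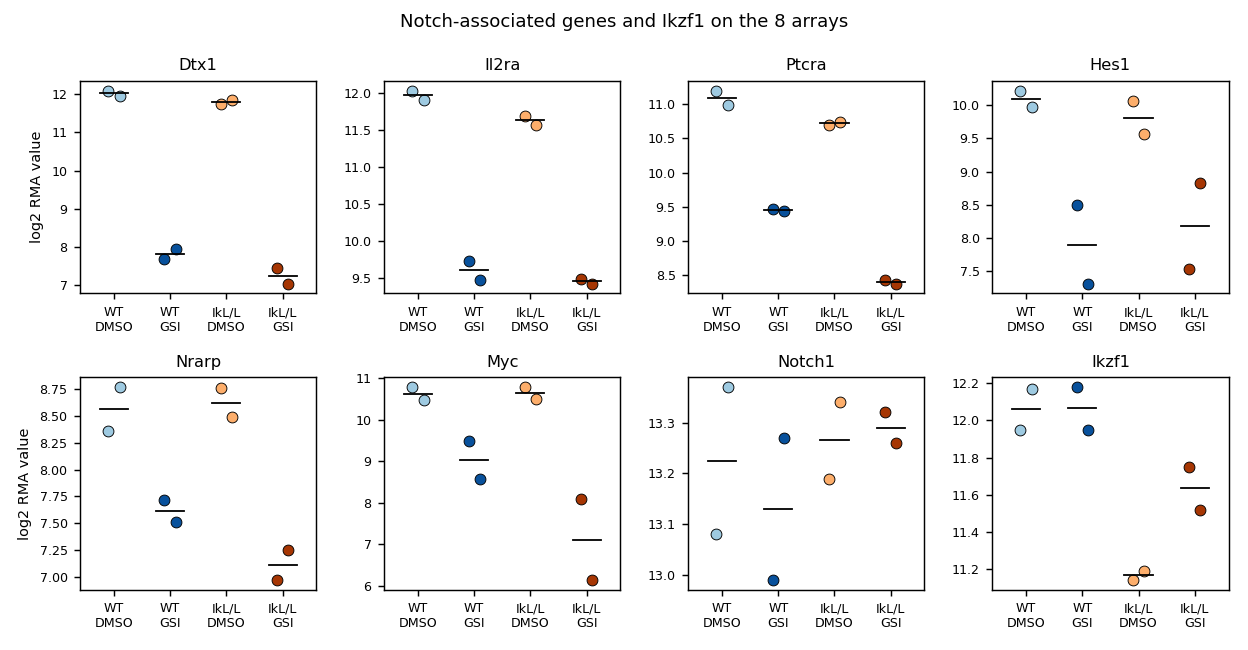
Log2 RMA values (y axis, a separate range in each panel) of 8 genes on the 8 arrays, by genotype and treatment (x axis). Each point is an array and each black line a group mean of 2 arrays. Dtx1, Il2ra, Ptcra, Nrarp and Myc lie lower on every GSI array than on the DMSO arrays of the same genotype, Notch1 arrays overlap between treatments, and Ikzf1 lies lower on the IkL/L arrays.

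The response to GSI was tested first as the average over both genotypes. Of the genes listed beforehand, 10 of 19 Notch targets, 29 of 30 ribosome biogenesis, 27 of 28 G1/S and 21 of 29 G2/M genes fell, while 8 of 21 FOXO or quiescence and 7 of 21 progenitor genes rose. None of these lists passed camera, limma's competitive test of gene lists, with an estimated inter-gene correlation (adjusted p between 0.31 and 0.41). That form of camera passed no list in any contrast, so failing it says little about a single list. For FOXO genes the camera adjusted p was 5.86e-05 at the preset correlation of 0.01. It was 0.312 with the estimate, although that estimate was only 0.016. Dtx1, encoding the Notch-pathway ubiquitin ligase Deltex, had the largest decrease of the named genes and fell by 4.38 ± 0.14 on the log2 scale (SE; 20.8-fold; limma, adjusted p = 1.6e-05). It was lower on each of the 4 GSI arrays than on the DMSO arrays of its genotype. Of the 19 Notch targets measured, 10 fell, 1 rose and 8 did not pass (10 and 1 adjusted over the list alone). They included Il2ra (-2.27 ± 0.11), which encodes the CD25 used in the sort, and Ptcra (-1.99 ± 0.11), encoding the pre-T cell receptor alpha chain. They also included the repressor gene Hes1 (-1.91 ± 0.34), the feedback inhibitor gene Nrarp (-1.23 ± 0.16) and Myc (-2.57 ± 0.40). The member that rose was Cdkn1a, encoding the cell cycle inhibitor p21 (2.27 ± 0.10). The receptor genes Notch1 (-0.04 ± 0.09) and Notch3 (0.01 ± 0.21) did not pass, and their signs turned under other scalings.

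Of 30 genes of ribosome biogenesis and other MYC-activated functions, 29 fell (30 adjusted over the list alone), with a median log2 change of -1.49. Among them were the spermidine synthase gene Srm (-3.11 ± 0.23), the pyrimidine synthesis gene Cad (-2.57 ± 0.19) and Nolc1 (-2.40 ± 0.21). Of 28 G1/S genes 27 fell (27 adjusted over the list alone; median -1.31). They included the replication genes Cdc6 (-2.16 ± 0.21) and Gins1 (-1.87 ± 0.11). Of 29 G2/M genes 21 fell (24 adjusted over the list alone; median -0.67), such as Aurkb (-1.52 ± 0.16). Of 18 glycolysis genes 9 fell, led by the hexokinase gene Hk2 (-2.84 ± 0.21), and 3 rose (11 and 4 adjusted over the list alone). Without any of the 4 IkL/L arrays in turn, 1 glycolysis gene rose. Ribosomal protein genes had a median of 0.02, with 1 of 17 higher and 2 lower. With a single array left out in turn, 26 to 29 of the ribosome biogenesis genes, 25 to 27 of the G1/S genes and 13 to 23 of the G2/M genes fell. The log2 difference between the 3' and 5' GAPDH control probe sets, a sign of RNA length, was larger on GSI than on DMSO arrays of the same genotype. It was 1.71 and 2.12 in WT DMSO, 2.20 and 3.08 in WT GSI, 1.87 and 2.47 in IkL/L DMSO, and 3.09 and 3.03 in IkL/L GSI.

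Of 21 FOXO-activated or quiescence genes 8 rose and none fell (9 adjusted over the list alone; median 0.51). Among them were Pik3ip1 (1.35 ± 0.12), Bcl6 (1.32 ± 0.14) and Foxo3 (0.98 ± 0.15). Without IkL/L DMSO replicate 1, 4 rose, and without IkL/L DMSO replicate 2 or either IkL/L GSI array, 5. Among the 16 genes of the BCL2 family and cell death 4 rose, 1 fell and 11 did not pass (4 and 1 adjusted over the list alone; median -0.04), and the list did not pass camera (adjusted p = 0.39). The BH3-only gene Bmf (1.68 ± 0.13) and the survival gene Mcl1 (0.99 ± 0.08) rose, and Bid fell (-2.23 ± 0.27). Without WT GSI replicate 1, 3 of the list fell. Of 21 progenitor genes 7 rose (8 adjusted over the list alone), and 4 rose without IkL/L DMSO replicate 2. Examples were Nfe2 (1.96 ± 0.26), Cd93 (1.5 ± 0.19), Erg (1.44 ± 0.20) and the receptor gene Kit (1.0 ± 0.19). Named increases included Sh2d5 (2.86 ± 0.17), the mast cell protease gene Cpa3 (2.72 ± 0.26), Rasa4 (2.61 ± 0.14) and the chemokine receptor gene Ccr9 (2.51 ± 0.09). Of 22 interferon-stimulated genes 5 rose (10 adjusted over the list alone; median 1.22), such as Rsad2 (2.01 ± 0.58). Leaving out a single array gave between 0 (without IkL/L GSI replicate 1) and 15 (without WT GSI replicate 2). In turn 14 rose without both WT arrays numbered 1, 19 with the stromal level and 20 with the GAPDH difference as a covariate. The mean level of that list differed between replicates and was higher on the GSI array than on the DMSO array of the same genotype and number, although the numbers are not known to pair the samples. It was 9.15 and 7.49 in WT DMSO, 10.3 and 8.81 in WT GSI, 8.22 and 7.22 in IkL/L DMSO, and 9.37 and 8.56 in IkL/L GSI.

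In all, 4235 genes changed in the average (limma, adjusted p below 0.05; 1964 higher, 2271 lower), 1323 of them at least 2-fold. By camera with a preset inter-gene correlation 13 of 28 lists passed, and none did with an estimated correlation. The adjusted p was then 0.41 for Notch targets, 0.41 for ribosome biogenesis, 0.31 for G1/S, 0.41 for G2/M and 0.49 for glycolysis. It was 0.31 for FOXO genes, 0.41 for progenitor genes and 0.51 for interferon-stimulated genes. By fry 13 lists passed, with an adjusted p of 0.00125 for Notch targets and G1/S, 0.00407 for ribosome biogenesis and FOXO genes and 0.00678 for G2/M. The fry adjusted p was 0.0137 for progenitor genes, 0.0174 for glycolysis and 0.173 for interferon-stimulated genes. The count of genes was 2616 without IkL/L DMSO replicate 1, and 6623 when every probe set was counted. With the GAPDH difference as a covariate the balance of directions turned, to 2245 higher and 1438 lower (61.0% higher, against 46.4% without it), and 2338 of the 4235 genes were called again. Without WT GSI replicate 2 it was 2089 higher and 2018 lower. Of 114 called genes followed by name, 95 kept their call without each of the 8 arrays in turn.

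**Figure D2:**
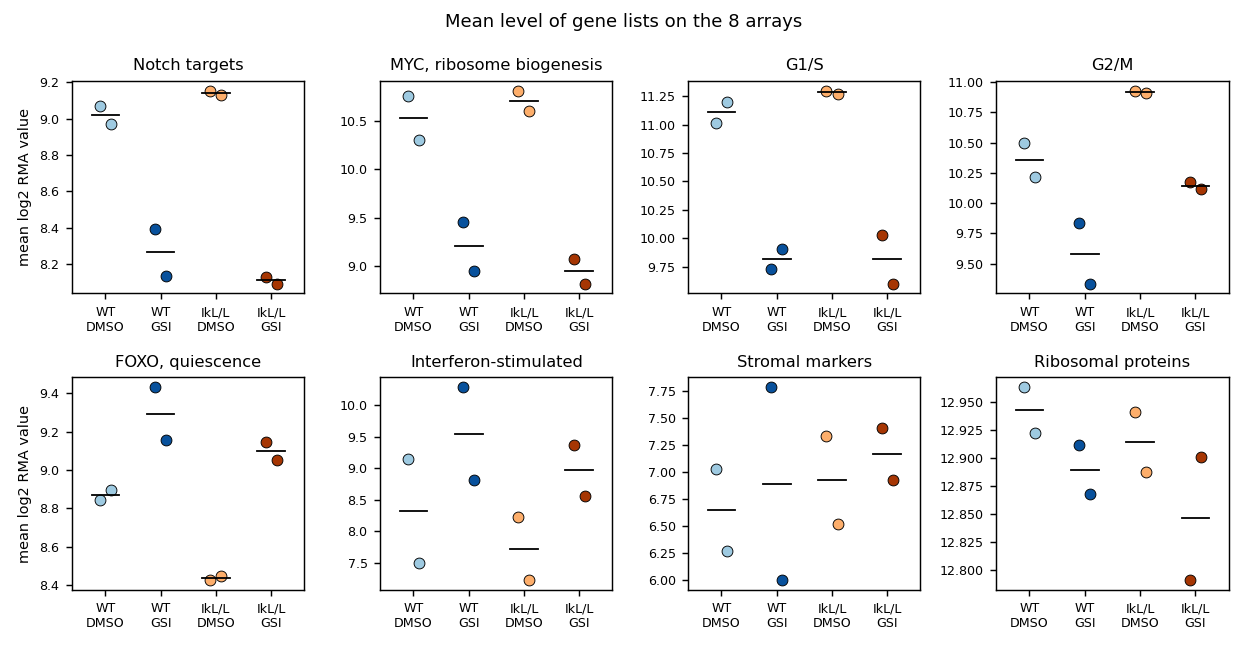
Mean log2 RMA value of 8 gene lists (y axis, a separate range in each panel) on the 8 arrays, by genotype and treatment (x axis). Each point is an array and each black line a group mean of 2 arrays. Notch target, ribosome biogenesis and G1/S levels lie lower on every GSI array than on every DMSO array, interferon-stimulated and stromal levels differ widely between replicates, and ribosomal protein levels span less than a log2 unit.

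In WT cells treated with GSI, Dtx1 fell by 4.20 on the log2 scale (SE 0.20; 18.4-fold; adjusted p = 0.00036), from 12.02 ± 0.09 to 7.82 ± 0.20 (SD, n = 2). Of 19 Notch targets 6 fell and 1 rose (9 and 3 adjusted over the list alone). Those that fell included Il2ra (-2.37 ± 0.15), Hes1 (-2.20 ± 0.48), the kinase-like gene Trib2 (-1.89 ± 0.35) and Ptcra (-1.64 ± 0.15). Myc was at -1.61 ± 0.57 and did not pass (adjusted p = 0.15). Of 30 ribosome biogenesis genes 20 fell (29 adjusted over the list alone; median -1.31), of 28 G1/S genes 22 (27; median -1.20) and of 29 G2/M genes 11 (20; median -0.67). Examples were Srm (-2.56 ± 0.32), Mcm3 (-1.71 ± 0.24) and Cdk1 (-1.37 ± 0.20). Cdkn1a (1.64 ± 0.15), Ccr9 (1.5 ± 0.13) and the surface glycoprotein gene Cd52 (2.24 ± 0.18) rose. FOXO genes included 3 of 21 that rose (4 adjusted over the list alone) and none of the 21 progenitor genes passed (2 adjusted over the list alone). In total 1177 genes changed (421 higher, 756 lower), 674 at least 2-fold, and 13 of 28 lists passed camera. None passed with an estimated correlation, where the adjusted p was 0.31 for Notch targets, ribosome biogenesis, G1/S, G2/M and FOXO genes and 0.54 for progenitor genes.

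The WT count rested on single arrays and on the shared estimate of spread. Leaving out an IkL/L array changed it only through that estimate, as the WT log2 changes stayed the same. With the replicate number as a block it was 1973, although the numbers are not known to pair the samples. In all, 9 genes passed without WT DMSO replicate 1, 186 without WT DMSO replicate 2, and 678 without WT GSI replicate 2. There were 395 and 421 without IkL/L DMSO replicates 1 and 2, 764 and 761 without IkL/L GSI replicates 1 and 2. The count was 1 with only the 4 WT arrays in the fit and 543 without both WT arrays numbered 1. Without WT DMSO replicate 1, 2 Notch targets and none of the ribosome biogenesis, G1/S, G2/M or FOXO genes passed. Of 73 called genes followed by name, Afdn, Bex6, Cd52, Dtx1, Il2ra, Nln and Pou2af1 kept their call without each of the 8 arrays in turn, and with only the 4 WT arrays 1 of the 73 did. The mean level of stromal marker genes was 7.03 and 6.27 on the WT DMSO arrays, 7.79 and 6.0 on the WT GSI arrays. It was 7.34 and 6.52 on the IkL/L DMSO arrays and 7.41 and 6.92 on the IkL/L GSI arrays. With that level as a covariate 3165 genes passed. The level was higher on the array numbered 1 in every group, so this fit overlaps with a block by replicate number. As probe sets 711 passed. With the GAPDH difference as a covariate 2276 passed, of which 60.6% were higher, against 35.8% without it.

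In IkL/L cells treated with GSI, Dtx1 fell by 4.55 on the log2 scale (SE 0.20; 23.4-fold; adjusted p = 9.5e-05). In all, 9 of 19 Notch targets fell while 1 rose (10 and 1 adjusted over the list alone), and those that fell included Myc (-3.53 ± 0.57), Ptcra (-2.33 ± 0.15), Il2ra (-2.18 ± 0.15) and Nrarp (-1.51 ± 0.22). Hes1 was at -1.63 ± 0.48 and did not pass (adjusted p = 0.054). Of 30 ribosome biogenesis genes 27 fell (30 adjusted over the list alone; median -1.71), of 28 G1/S genes 24 (27; median -1.44) and of 29 G2/M genes 13 (18; median -0.79). Examples were Srm (-3.67 ± 0.32), Cad (-3.13 ± 0.27) and Gins1 (-2.10 ± 0.16). The named genes with the largest increases included Rasa4 (3.72 ± 0.20), the MHC class II gene H2-Aa (3.69 ± 0.30), Ccr9 (3.52 ± 0.13), Atp8b4 (3.12 ± 0.15) and the lysozyme gene Lyz1 (3.09 ± 0.27). Of 21 progenitor genes 7 rose (7 adjusted over the list alone), led by Nfe2 (2.42 ± 0.37) and Erg (2.12 ± 0.28). In addition 6 of 21 FOXO genes rose (9), led by Pik3ip1 (1.84 ± 0.17), and 6 of 18 p53 targets rose and 1 fell (6 and 2), led by Cdkn1a (2.90 ± 0.15), while Aen fell (-1.57 ± 0.35). Of 22 myeloid and dendritic markers 8 rose and none fell (8 and 1 adjusted over the list alone): H2-Aa, H2-Eb1 (2.23 ± 0.23), H2-Ab1 (1.21 ± 0.24), Cd74 (1.98 ± 0.24), Lyz1, Lyz2 (2.5 ± 0.26), S100a8 (1.71 ± 0.26) and S100a9 (1.47 ± 0.15). H2-Ab1, Cd74, S100a8 and S100a9 lay outside the naming rule here and were named after their values were seen.

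In total 3055 genes changed in IkL/L (1401 higher, 1654 lower), 1766 at least 2-fold, and 14 of 28 lists passed camera. None passed with an estimated correlation, where the adjusted p was 0.39 for Notch targets, ribosome biogenesis, G1/S, G2/M, progenitor, p53 and myeloid genes and 0.32 for FOXO genes. The count was 947 and 1330 without IkL/L DMSO replicates 1 and 2 and 1807 and 1080 without IkL/L GSI replicates 1 and 2. In those fits 16 to 22 ribosome biogenesis, 16 to 24 G1/S, 3 to 9 G2/M and 7 to 9 Notch target genes fell, while 3 to 7 progenitor, 2 to 3 FOXO, 1 to 4 p53 and 7 myeloid genes rose. Of 101 called genes followed by name, 64 kept their call without each array in turn. With the stromal level as a covariate 5185 genes passed. With the GAPDH difference as a covariate 61.3% of called genes were higher, against 45.9% without it, and 1946 of the 3055 genes were called again.

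**Figure D3:**
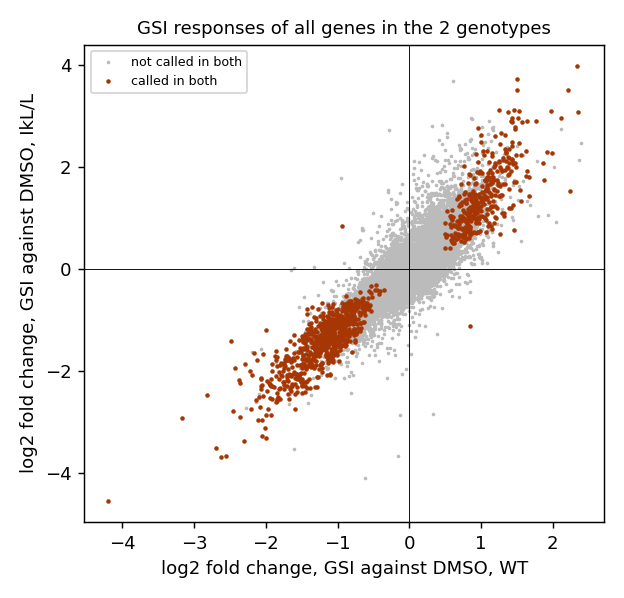
Log2 fold change with GSI in WT (x axis) and in IkL/L (y axis) for each of the 18193 genes. Each point is a gene, coloured where it passed the test in both genotypes; 1064 such genes lie in the same direction and 2 in opposite directions.

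The responses of the genotypes were set against each other in comparisons that shared no arrays. Both used the same estimate of each gene's spread. Genes with a small spread tend to be called in both, so the expected counts are likely too low. Of the genes called in both, 357 were higher in both (32.4 expected for independent lists) and 707 lower in both (68.7 expected), and 2 went in opposite directions (96.5 expected). The log2 changes correlated across genes with Pearson's r = 0.841 and Spearman's rho = 0.724, where genes are not independent replicates. Among genes called in WT, the slope of the IkL/L change on the WT change was 1.19, and among genes called in IkL/L the slope of the WT change on the IkL/L change was 0.62.

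The difference between the responses themselves was tested as an interaction, and 8 genes passed (limma; 5 with a more positive and 3 with a more negative response in IkL/L), with 1089 genes at an unadjusted p below 0.05. Ccr9 rose by 1.5 ± 0.13 in WT and 3.52 ± 0.13 in IkL/L, a difference of 2.02 ± 0.18 (adjusted p = 0.028). Its levels were 11.57 ± 0.08 in WT DMSO, 9.46 ± 0.04 in IkL/L DMSO, 13.07 ± 0.18 in WT GSI and 12.98 ± 0.07 in IkL/L GSI (SD, n = 2). Atp8b4, encoding a phospholipid flippase, had a difference of 1.87 ± 0.21 and a like order of levels. Rab44 (3.0 ± 0.29), Muc3 (2.07 ± 0.22) and Mctp1 (1.67 ± 0.16) rose in IkL/L, by 2.72, 2.59 and 1.79, against changes of -0.28, 0.52 and 0.12 in WT. Exoc3l4 (-2.74 ± 0.31) fell in IkL/L from 7.13 ± 0.45 to 4.26 ± 0.19 and was near 4 in both WT groups. Spsb4 (-3.49 ± 0.51, adjusted p = 0.13), H2-Aa (3.09 ± 0.42, adjusted p = 0.096) and Cdkn1a (1.26 ± 0.21, adjusted p = 0.18) did not pass, nor did Dtx1 (-0.35 ± 0.28), Hes1 (0.57 ± 0.68) or Myc (-1.92 ± 0.80).

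Among the lists, ribosome biogenesis genes had a more negative median response in IkL/L (-0.46), FOXO genes (0.18) and myeloid and dendritic markers (0.11; 7 of 22 adjusted over the list alone) a more positive response, by camera. No member of these 3 lists passed singly over all genes, and with an estimated correlation the adjusted p was 0.94, 0.63 and 0.71. None of the 8 genes kept its call without each array in turn. By limma 0 genes passed without WT DMSO replicate 1 or IkL/L DMSO replicate 1 (1398 and 627 at an unadjusted p below 0.05), 1 without IkL/L GSI replicate 1, 2 without any of 4 other arrays and 5 without WT GSI replicate 1. With every probe set as a feature or without both WT arrays numbered 1, 0 passed (2270 and 1560 unadjusted). In turn 57 passed with the stromal level and 64 with the GAPDH difference as a covariate.

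**Figure D4:**
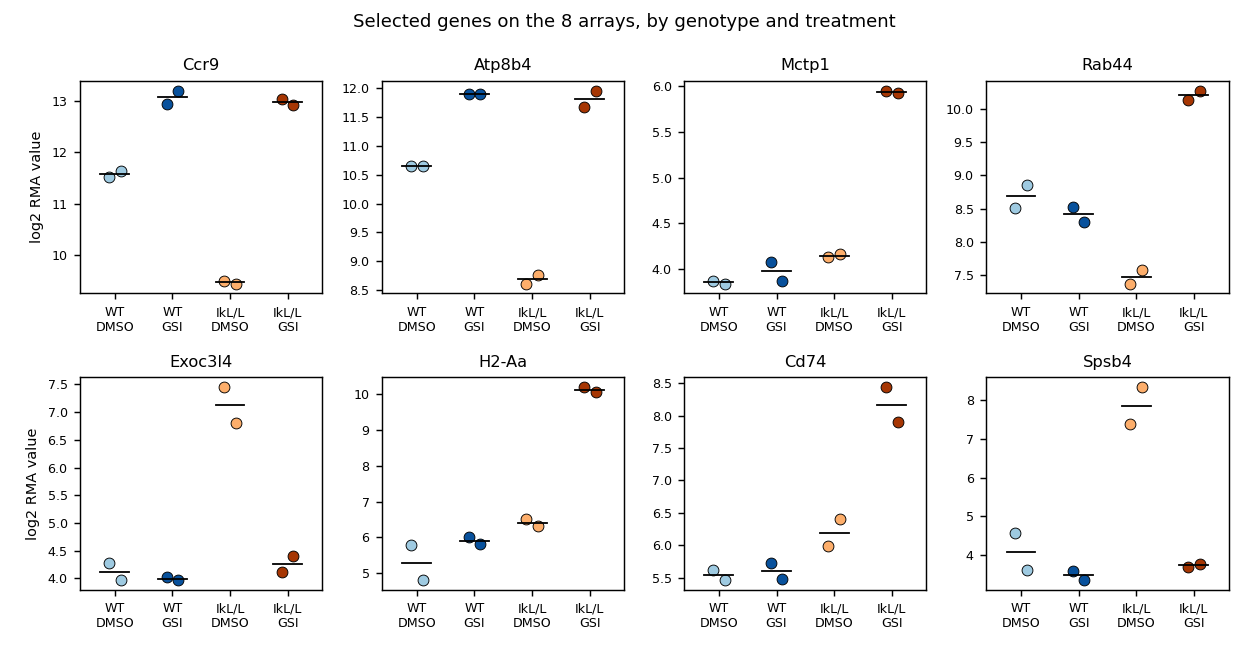
Log2 RMA values (y axis, a separate range in each panel) of 8 genes on the 8 arrays, by genotype and treatment (x axis). Each point is an array and each black line a group mean of 2 arrays. Ccr9 and Atp8b4 lie lowest on the IkL/L DMSO arrays, H2-Aa, Cd74, Rab44 and Mctp1 lie highest on the IkL/L GSI arrays, and Exoc3l4 and Spsb4 lie highest on the IkL/L DMSO arrays.

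Under DMSO, Scin, encoding the actin-severing protein scinderin, was lower in IkL/L than in WT by a log2 difference of -5.27 ± 0.41 (SE; 38.6-fold; adjusted p = 0.001). The adhesion genes Cdh1 (-3.09 ± 0.18), encoding E-cadherin, and Itgae (-2.84 ± 0.19), encoding its integrin ligand CD103, were also lower. So were Sytl4 (-3.22 ± 0.21), Rasa4 (-2.92 ± 0.20), the transcription factor gene Spib (-2.42 ± 0.23) and Ccr9 (-2.11 ± 0.13). Higher in IkL/L were Ptgfrn (4.35 ± 0.26), Dock1 (3.97 ± 0.21), Spsb4 (3.76 ± 0.36) and the catenin gene Ctnnd1 (3.50 ± 0.30). Of 19 Notch targets, Uaca (2.74 ± 0.24) and Igf1r (1.33 ± 0.26) were higher, Cdkn1a was lower (-0.98 ± 0.15) and 16 did not pass (4 higher and 1 lower adjusted over the list alone). Dtx1 (-0.24 ± 0.20), Hes1 (-0.28 ± 0.48) and Myc (0.01 ± 0.57) were among those. Of 21 FOXO genes Pik3ip1 (-0.92 ± 0.17) and Btg1 (-0.93 ± 0.18) were lower (4 adjusted over the list alone; median -0.30). None of 29 G2/M genes passed singly, with a median of 0.57, and none of 22 interferon-stimulated genes did, with a median of -0.66. Of 22 myeloid and dendritic markers 1 was higher, the MHC class II gene H2-Ab1, and none lower (3 higher adjusted over the list alone). The Y-linked genes Eif2s3y (6.21 ± 0.32), Kdm5d (4.78 ± 0.37) and Uty (3.87 ± 0.32) were higher in IkL/L. Xist, expressed from an inactive X chromosome, was lower (-1.3 ± 0.19) but still at a level of 11.49 ± 0.13 (SD, n = 2), so that the IkL/L arrays carried both signals. By these genes the genotypes were not balanced for sex.

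In total 316 genes differed under DMSO (129 higher, 187 lower), 266 at least 2-fold. By camera 6 of 28 lists passed, and none did with an estimated correlation. The adjusted p was then 0.62 for G2/M, 0.31 for FOXO and 0.86 for interferon-stimulated genes, 0.86 for G1/S genes (median 0.15) and myeloid markers (median 0.12), and 0.42 for the sex-linked genes. The count was 112 and 93 without WT DMSO replicates 1 and 2, 76 and 81 without IkL/L DMSO replicates 1 and 2. It was 210 and 206 without IkL/L GSI replicates 1 and 2, and 186 in probe sets. The balance turned to 52 higher and 41 lower without WT DMSO replicate 2, 40 and 36 without IkL/L DMSO replicate 1, 46 and 35 without IkL/L DMSO replicate 2, and 97 and 89 in probe sets. The count was 843 with the stromal level and 1063 with the GAPDH difference as a covariate. Of 47 called genes followed by name 23 kept their call without each array in turn, among them Scin, Cdh1, Itgae, Sytl4, Rasa4, Spib, Ccr9, Ptgfrn, Dock1, Spsb4, Ctnnd1, Uaca and the 3 Y-linked genes. Calls were lost for Igf1r, Cdkn1a, Pik3ip1, Btg1, H2-Ab1, Xist and Ikzf1.

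Under GSI, IkL/L cells were higher than WT in MHC class II genes: H2-Aa by 4.21 ± 0.30 on the log2 scale (18.5-fold; adjusted p = 0.0005), H2-Ab1 by 2.64 ± 0.24, H2-Eb1 by 2.17 ± 0.23 and the invariant chain gene Cd74 by 2.57 ± 0.24. These genes present peptides on antigen-presenting cells. They stood in a list of 22 myeloid and dendritic markers of which 8 were higher and none lower (8 and 1 adjusted over the list alone; median 0.21), with the lysozyme genes Lyz1 (1.77 ± 0.27), Lyz2 (1.61 ± 0.26) and the neutrophil and monocyte genes S100a8 (1.41 ± 0.26) and S100a9 (1.08 ± 0.15) beside them; these last 4 were named after their values were seen. The cytokine gene Il6 (3.66 ± 0.35), Rassf4 (3.62 ± 0.23), Dock1 (3.34 ± 0.21), the keratin gene Krt18 (3.31 ± 0.21) and the haematopoietic transcription factor gene Tal1 (1.80 ± 0.20) were also higher. Grasp (-3.43 ± 0.24), Cdh1 (-3.29 ± 0.18), Gpr25 (-2.91 ± 0.19), Scin (-2.78 ± 0.41) and Itgae (-2.71 ± 0.19) were lower. Of 19 Notch targets Uaca (1.97 ± 0.24) and Igf1r (1.78 ± 0.26) were higher and Ptcra lower (-1.06 ± 0.15), with 2 higher and 6 lower adjusted over the list alone. None of 29 G2/M genes passed (4 adjusted over the list alone), with a median of 0.55. The Y-linked genes were higher here too, Eif2s3y by 6.99 ± 0.32.

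In total 266 genes differed under GSI (172 higher, 94 lower), 232 at least 2-fold. Under both treatments 76 genes were higher and 49 lower in IkL/L (1.22 and 0.97 expected for independent lists). These comparisons shared no arrays but did share the estimate of each gene's spread, so the expected counts are likely too low. By camera 3 of 28 lists passed, and none did with an estimated correlation. The adjusted p was 0.58 for myeloid markers, 0.58 for G2/M and 0.29 for the sex-linked genes. The count was 101 with only the 4 GSI arrays, 141 and 100 without IkL/L GSI replicates 1 and 2, and 172 without either IkL/L DMSO array. It was 154 in the more highly expressed genes (above the median level), 858 with the stromal level and 794 with the GAPDH difference as a covariate. Of 44 called genes followed by name 25 kept their call without each array in turn, among them the 4 MHC class II genes, Il6, Rassf4, Dock1, Krt18, Tal1, Cdh1, Grasp, Gpr25 and Itgae. Calls were lost for Scin, the lysozyme and S100 genes, Uaca, Igf1r and Ptcra. Without WT GSI replicate 2 or IkL/L GSI replicate 1, 4 of the 22 myeloid markers were higher.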

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

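The tests of RNA quality, stromal RNA, myeloid and B cells, the sex of the mice, and DNA near Ikzf1 as the whole cause, and the recount near Ikzf1 without each array, were chosen only after the results were seen; those of a level-dependent shift, of DNA flanking Ikzf1 and of other splits of the arrays were planned.

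The response to GSI differed between the genotypes, by the test of the interaction, for 8 genes. The IkL/L response minus the WT response was -3.52 for Gm266, 3.0 for Rab44, -2.74 for Exoc3l4, 2.07 for Muc3, 2.02 for Ccr9, -1.97 for 2810459M11Rik, 1.87 for Atp8b4 and 1.67 for Mctp1 on the log2 scale. Gm266 and 2810459M11Rik lay outside the naming rule and were named after their values were seen. None of the 8 calls held without each array in turn.

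A further signal lay in the 10092 probe sets that name no single gene, which no comparison of genes used. Of these, 753 changed with GSI in the average over both genotypes, 390 higher and 363 lower. The largest log2 values were 3.11 and 2.95 upward and -2.85 and -2.83 downward.

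The lower level of ribosome biogenesis and G1/S genes with GSI (58 members, median -1.43, SE 0.09, 56 called) was weighed first. Each SE of a median, here and for the MHC class II genes below, comes from the spread between genes taken as independent. It does not measure the spread between arrays. With the GAPDH 3' minus 5' difference as a covariate the median was -1.23 (SE 0.12) and 47 members were called. With the groups in that fit, its slope rests only on differences between replicates, which overlap with the replicate number. The GAPDH difference between treatments is confounded with GSI, so this fit does not decide on RNA quality. Genes matched on level had a median of -0.02 (SE 0.04), but quantile normalization between arrays tends to hold such a median near 0. The stromal level as a covariate gave -1.50 (SE 0.09). The stromal list itself had a median change of 0.24 with GSI and 0 of 19 members called, so that covariate could hardly move the value. Neither test therefore decides on a level-dependent shift or on stromal RNA. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the split by treatment, called as many as 3546 genes, and the highest other called 139, the split by genotype; this argues against chance only if the arrays are independent samples, which the labels do not state. An effect of blocked Notch processing may underlie the pattern, as a hypothesis, and an effect of the inhibitor on other substrates was not tested.

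Under DMSO, H2-Ab1 was the only 1 of the 22 myeloid and dendritic markers called higher in IkL/L than in WT. Under GSI, the MHC class II genes and Cd74 were higher in IkL/L than in WT (4 members, median 2.61, SE 0.56 over genes). The B lineage list had a median of -0.15 (SE 0.25), which argues against B cells in the sort as the whole cause, although Igll1 was called higher (1.03 ± 0.17), a call kept in 2 of the 8 fits without an array. The other 18 myeloid and dendritic markers had a median of 0.10 (SE 0.20), but 4 of them were called higher: Lyz1 (1.77), Lyz2 (1.61), S100a8 (1.41) and S100a9 (1.08). Myeloid or dendritic cells in the sort, which the lineage depletion and gate would remove, therefore cannot be told apart from expression in DN3 cells, since some markers rose and others did not. An effect of the genotype stays open, and the interaction for H2-Aa did not pass (3.09, adjusted p = 0.096).

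Among the genes that differ between IkL/L and WT, the Y-linked genes differed by a mean log2 value of 5.2. The sex of the mice and the genotype cannot be told apart, since the Y-linked genes were at background in every WT array, while the IkL/L arrays carried both Y-linked and Xist signal (Xist 11.49 under DMSO and 11.85 under GSI), so that whether they held cells of both sexes stays open. Of the 100 genes nearest to Ikzf1, 8 were called in either genotype comparison (2.5 expected; one-sided Fisher's exact p = 0.0036): Ddc, Cnrip1, Camk2b, Pgam2, Ccdc117, Emid1, Gas2l1 and Nefh, named after their values were seen, so flanking DNA of another strain may contribute. Without a single array the count was 3 to 9, with 3 (1.12 and 1.13 expected; one-sided Fisher's exact p = 0.1 each) without either IkL/L DMSO array and 4 (p = 0.067, 0.075 and 0.048 by the same Fisher's exact test) without WT DMSO replicate 1 or either IkL/L GSI array, and only Ddc kept its call throughout. The other 447 of the 455 called genes lay outside the 100 nearest to Ikzf1. This count does not decide whether flanking DNA is the whole cause, since 100 genes could not hold most of 455 calls. A longer flanking segment and effects of flanking genes on genes elsewhere were not tested. An effect of the loss of Ikaros stays open.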

How the results depend on the processing

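The fits without both WT arrays numbered 1 and with the stromal level or the GAPDH difference as a covariate, and the count of signs over all called genes, were chosen only after the results were seen; the others were planned. Dim probe sets near background compress differences, which limits genes at low level. Centring moved the share of higher calls in WT from 35.8% to 27.5%, and the GAPDH covariate moved it to 60.6%, from 45.9% to 61.3% in IkL/L and from 46.4% to 61.0% in the average. No value past the threshold reversed among the genes followed by name. Over all genes, 14 of the 4235 called in the average reversed with the GAPDH covariate, and 15 of the 4235 and 16 of the 3055 called in IkL/L did with a mean over probe sets, none past the threshold there. Where a value below moved, the cause was not tested, except that fewer arrays or genes, a 2-fold minimum or more features change a count by construction.

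With the replicate block, which the labels' numbers may not justify since replicate differences correlated at 0.71, 0.579 and 0.562 among WT DMSO, WT GSI and IkL/L DMSO but at -0.113, 0.025 and -0.01 with IkL/L GSI, the counts were 1973 for GSI in WT, 24 for the interaction, 542 and 470 for the genotype under DMSO and GSI, 6 and 7 lists for the interaction and the genotype under GSI, and 1775 genes in the overlap of GSI responses. With it 20 of 22 interferon-stimulated genes rose in the average. The camera adjusted p of that list at the preset correlation was 3.64e-12 with the block and 2.58e-05 without it. Without the block it was 0.51 by camera with an estimated correlation of 0.796, and 0.173 by fry. Under the block 580 of 616 gene values kept their side of the threshold and 36 newly passed. A block within genotype gave 3005, 4986 and 112 for GSI in WT, in IkL/L and the interaction.

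With all probe sets as features, 711 changed in WT, 6623 in the average, 0 in the interaction (limma, 2270 at an unadjusted p below 0.05) and 186 between genotypes under DMSO. Only the arrays compared gave 1 for GSI in WT and 101 for the genotype under GSI. Without both WT arrays numbered 1 there were 543 for GSI in WT and 0 for the interaction (1560 unadjusted). The stromal covariate gave 3165, 5185, 57, 843 and 858 for GSI in WT, in IkL/L, the interaction and the genotype under DMSO and GSI, and the GAPDH covariate 2276, 64, 1063 and 794 for these without IkL/L. Within every group the stromal level was higher on the array numbered 1. The GAPDH difference was lower on that array in all groups but IkL/L GSI. Both covariate fits thus overlap with the replicate block. A 2-fold minimum left 674, 1766 and 1323 for GSI in WT, in IkL/L and the average. Genes above the median level gave 2 for the interaction and 154 for the genotype under GSI, and eBayes without a trend 2 for the interaction. By camera with an estimated correlation 0 lists passed in each of the 6 contrasts. Even the sex-linked list for the genotype under GSI did not pass. Its camera adjusted p was 0.288 at an estimated correlation of -0.124, against 7.02e-05 at the preset one. Failing that form therefore says little about a single list. By fry 8 passed for GSI in WT, 11 in IkL/L, 13 in the average, 0 for the interaction and 1 for each genotype contrast. Without a single array the counts ranged from 9 to 1341 for GSI in WT, 947 to 3860 in IkL/L, 2616 to 4642 in the average, 0 to 5 for the interaction (627 to 1704 unadjusted), 76 to 425 under DMSO and 100 to 238 under GSI.

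The signs of these values not past the threshold reversed. With a mean over probe sets, Notch1 was at -0.20 for GSI in IkL/L, Notch3 at -0.16 in the average, Sox4 at -0.29 in the interaction, Lyz1 and Nrarp at -0.03 and -0.04 under DMSO, and Atp8b4 at 0.05 under GSI. With centring, Ikzf1 was at -0.04 for GSI in WT, Notch1 at -0.03 for GSI in IkL/L and Notch3 at -0.04 in the average, and with quantile normalization Notch1 was at 0.02 in the average.

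Lowest and highest values without a single array were, for GSI in WT, 2810459M11Rik (-0.24, 0.04), Col1a2 (-0.92, 1.84), Eif2s3y (-0.62, 0.22), Exoc3l4 (-0.27, 0.01), Ikzf1 (-0.11, 0.12), Jun (-0.35, 2.18), Notch1 (-0.24, 0.05), Notch3 (-0.54, 0.23) and Thbs1 (-0.45, 1.53). For GSI in IkL/L they were Notch1 (-0.05, 0.10) and Notch3 (-0.01, 0.35), and in the average Bgn (-0.04, 1.09), Kdm5d (-0.11, 0.59), Notch1 (-0.11, 0.04) and Notch3 (-0.18, 0.20). In the interaction they were Fos (-1.92, 4.54), Hes1 (-0.08, 1.22), Hspa1a (-0.09, 1.80), Ifit2 (-1.50, 0.07), Ifit3 (-2.79, 1.01), Notch1 (-0.02, 0.26), Notch3 (-0.06, 0.71), Plk1 (-1.0, 0.31), Serpinf1 (-0.75, 1.66), Tbx21 (-1.04, 0.09), Tyms (-0.04, 1.62) and Uty (-0.02, 0.98). Under DMSO they were H2-Eb1 (-0.05, 0.36), Id2 (-0.86, 0.02), Lyz1 (-0.25, 0.36), Lyz2 (-0.30, 0.22), Muc3 (-0.16, 0.04), Myc (-0.15, 0.17), Ncstn (-1.18, 0.04), Notch1 (-0.10, 0.18), Nrarp (-0.15, 0.27), Rpl27a (-0.05, 0.41) and Rsad2 (-2.10, 0.18). Under GSI they were 2810459M11Rik (-0.04, 0.21), Aldoc (-0.11, 1.11), Atp8b4 (-0.24, 0.05), Ccr9 (-0.22, 0.04), Fdps (-0.01, 1.02), Fosb (-2.35, 0.10), Hes1 (-0.36, 0.93), Hspa1a (-0.03, 1.86), Ifit3 (-3.30, 0.50), Ifng (-2.06, 0.24), Klf2 (-2.08, 0.48), Klf4 (-4.69, 0.44), Mfng (-0.81, 0.11), Mgp (-3.30, 0.50), Ncstn (-0.29, 1.10), Notch3 (-0.59, 0.18), Tyms (-0.23, 1.44) and Uqcrc1 (-0.17, 0.98).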

Other observations

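The test of a link between the genotype difference and the GSI response, at the end, was chosen only after the result was seen. Members of further gene lists changed with GSI in the average over both genotypes. Of 24 ATF4 and amino acid genes 6 fell and 3 rose (6 and 3 adjusted over the list alone), among them the serine and folate pathway genes Shmt2 (-2.43 ± 0.18, SE), Mthfd2 (-2.17 ± 0.33) and Psat1 (-1.82 ± 0.17) and the amino acid transporter gene Slc7a5 (-1.71 ± 0.17). Of 27 respiratory chain genes 10 fell (11), such as Cycs (-1.17 ± 0.11), of 14 heat shock genes 7 fell (7), such as the mitochondrial chaperone gene Hspd1 (-1.82 ± 0.16), and of 18 cholesterol genes 6 fell and 1 rose (10 and 1), such as Idi1 (-1.19 ± 0.13) and Dhcr7 (0.99 ± 0.13). Of 18 p53 targets 6 rose and 2 fell (6 and 2), with Cdkn1a and the BH3-only gene Bbc3 (1.00 ± 0.20) higher and Aen lower (-1.35 ± 0.25). By camera the respiratory chain, heat shock and cholesterol lists passed, with an adjusted p of 0.49, 0.49 and 0.51 with an estimated correlation, and the ATF4 and p53 lists did not pass. Without a single array 5 to 17 respiratory chain genes and 4 to 11 cholesterol genes fell.

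Of 26 Notch pathway components 4 rose and 1 fell (3 and 0 adjusted over the list alone), with the fringe genes Lfng (0.97 ± 0.13) higher and Mfng (-0.81 ± 0.25) lower. Without a single array 2 to 5 of them rose and 0 to 1 fell, and Lfng kept its call in all 8 such fits but Mfng in 2. Of 22 T lineage genes 4 rose and 4 fell (6 and 4), including the transcription factor gene Lef1 (-1.11 ± 0.13), and of 19 genes of later thymocytes 4 rose and 5 fell (4 and 5), including Cd2 (-2.50 ± 0.40) and the transferrin receptor gene Tfrc (-1.52 ± 0.12). Of 5 Ikaros family genes, Ikzf2 (0.90 ± 0.20) and Ikzf4 (0.57 ± 0.17) rose and Ikzf3 (-1.37 ± 0.23) fell (2 and 1). Ikzf3 kept its call in all 8 fits without an array, Ikzf2 in 7 and Ikzf4 in 1. Of 26 cytokine and effector genes 3 rose and 3 fell (3 and 3), with Ctla4 (1.98 ± 0.19) and Icos (1.09 ± 0.13) higher. Of 22 myeloid markers 8 rose (9, with 1 lower), of 13 B lineage markers 3 rose and 1 fell (3 and 1), with Spib (1.91 ± 0.16) and Vpreb1 (1.80 ± 0.18) higher and Pou2af1 (-2.11 ± 0.12) lower, of 15 natural killer and innate lymphoid markers 3 rose (4), such as Rora (1.43 ± 0.11), and of 7 gamma-delta markers 2 rose and 1 fell (2 and 1). Without a single array 3 to 7 genes of later thymocytes and 1 to 3 cytokine and effector genes fell, and 2 to 5 natural killer and innate lymphoid and 0 to 2 gamma-delta markers rose. Of 16 immediate early genes 2 rose (2), while without WT GSI replicate 2, 8 rose, and without WT GSI replicate 1, 3 fell. By limma 0 of 19 stromal, 12 erythroid and 5 sex-linked genes passed, but 1 stromal gene rose without WT GSI replicate 2 and 2 sex-linked genes without IkL/L DMSO replicate 2. Only the Notch pathway and myeloid lists of this paragraph passed camera, with an adjusted p of 0.41 each with an estimated correlation.

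A hypothesis was tested from Ccr9 and other genes that were lower in IkL/L than in WT under DMSO and rose with GSI: IkL/L cells under DMSO may lie at the uninhibited end of the GSI response. Across genes, the genotype difference under DMSO had a covariance of -0.078 with the average GSI effect (r = -0.40 across genes, which are not independent replicates), outside the range of -0.00173 to 0.00166 simulated from noise alone. These contrasts share DMSO arrays, which the simulation takes into account. With the effect in WT, where shared arrays give 0.0244 on average, the covariance was -0.0476. With the effect in IkL/L, where they give -0.0244, it was -0.108. The simulation drew the noise of each gene and group independently. Replicate differences, however, correlated across genes at 0.71, 0.579 and 0.562 among WT DMSO, WT GSI and IkL/L DMSO. The simulated range is likely too narrow for such shared noise, and lying outside it does not exclude that noise. Of the 187 genes lower in IkL/L under DMSO, 143 rose and 7 fell with GSI in the average, against 10.8% and 12.5% of all genes, and of the 129 higher genes 57 fell and 17 rose. In WT alone, 78 of the 187 rose and 7 fell, while of the 129 higher genes only 10 fell and 5 rose, against 4.2% and 2.3% of all genes. The values lie in the direction of the hypothesis, but noise shared between genes was not excluded. The hypothesis was drawn from genes that enter these same values, so they are no independent test of it. The sex of the mice and the genotype are confounded here, and Dtx1 and Hes1 did not differ past the threshold under DMSO. As a set the 19 Notch targets, of which 10 fell with GSI in the average, were not higher in IkL/L under DMSO (median -0.09, with 2 called higher and 1 lower).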
